A study of Oryza sativa Japonica Group with 7 samples.

How the data were processed

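H3K27me3 was measured by ChIP-seq in crWT, SDG711OX, osdrm2 and WT-2 leaves, SDG711 binding by ChIP-seq with an antibody against SDG711, and DNA methylation by BS-seq in crWT and SDG711OX. Each of the 7 groups, taken from the sample titles, held 1 library.

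The authors deposited peak lists for the crWT, SDG711OX and SDG711 ChIP libraries. Per the file headers, these were called with MACS 1.4.0rc2 without a control library, at a p cutoff of 1e-05 for the 2 H3K27me3 lists and 1e-09 for SDG711, and they give tag counts per peak, a score (10 times the negative log10 of the caller's p) and a fold enrichment, which is a ratio to the background of the same library. For BS-seq, the authors deposited counts per cytosine, namely reads with C and reads with C or T, and the lowest listed number of reads was 4. For osdrm2 and WT-2, the deposited values are tag counts per gene with a gene length. The submitters' processing notes name Trimmomatic 0.32, Bowtie2 2.1.0 and SAMtools 0.1.17. The genome build, the methylation caller and the tool that counted tags per gene are not given in the sources used here. Depth was 20802056, 9438420 and 20533075 tags for the 3 peak lists, 11.9 and 8.50 reads per listed cytosine for crWT and SDG711OX, and 15268455 and 16477904 tags over genes for osdrm2 and WT-2.

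Peaks shared at least 1 bp to count as overlapping, and peaks were placed at random within their chromosomes 1000 times. Alternatives were a score of at least 100, a fold enrichment of at least 5, and overlap of at least 50% of the peak. Overlaps were computed with numpy rather than bedtools.

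Methylation levels were methylated reads over all reads, per context, over cytosines with at least 4 reads in both libraries, with Wilson intervals. Alternatives were no minimum beyond the deposited one, at least 10 reads, and the mean of per-cytosine levels. Bins of 200 bp (alternative 500 bp) with at least 4 such cytosines were compared by Fisher's exact test with the Benjamini-Hochberg adjustment within context, at an adjusted p of 0.05 and a difference of at least 40 points in CG, 20 in CHG and 10 in CHH (alternative: halved differences). Windows of 1 kb were assigned to a peak class when a peak covered at least 50% of them in 1 library and 0 bp in the other, or at least 50% in both. The median change per class was set beside 10000 sets of windows without H3K27me3 and SDG711 peaks, matched on the crWT level in classes of 5 points and on SDG711OX reads in 4 classes (1000 sets for alternatives). Windows needed at least 5 cytosines in CG or CHG and 10 in CHH.

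Tags per gene were scaled to the total over genes, with a pseudocount of 1, for genes with at least 50 scaled tags in the higher library. Alternatives were TMM factors from edgeR 4.0.16, no filter, and a pseudocount of 10. Ratios of named genes have exact conditional binomial intervals. List medians were ranked among 10000 random lists (1000 for alternatives) drawn from the same of 100 classes of mean tag density. An added alternative drew them from 20 classes of density with 5 classes of gene length each.

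The 10 gene lists (PRC2, DNA methylation, KNOX and WOX meristem genes, MADS and floral genes, flowering time, shoot architecture, diterpenoid clusters, leaf and housekeeping, seed, root), the comparisons and the alternatives above were fixed before the data were examined. Exceptions among the alternatives were the random lists matched also on gene length and the fold enrichment of at least 5 for SDG711 peaks, which were added later. The rule for named genes took members of these lists with up to 4 examples each by size of change, the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with at least 100 scaled tags, SDG711 itself, and the 10 peaks of highest enrichment in each class. Of those genes, the 2 highest and 2 lowest are printed, since no table gives them a name. No gene description table was at hand, so the part of the rule that asks for informative descriptions was not used.

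Several choices were made after the data were seen. Symbols had been paired with locus numbers from memory, and list members were checked against the supplied gene table, which is on another assembly. Of 93 members, 55 had a symbol on the same chromosome with a gene length within 1.5-fold, and 24 with no symbol in that table were kept, SDG711 among them. Left out were 8 members of other length, 2 on another chromosome, 2 out of order with lengths differing by more than 1.05-fold (CYP99A2 and CYP99A3), and 2 whose locus number was not listed (DRM2 and KSL7). These limits were set with the lengths and orders of the members in view, and lists without the check and with checked members alone were run as alternatives. The split by tag density, the mean change per window class, the runs of neighbouring genes and the remaining added alternatives were also chosen after seeing the data.

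Gene coordinates on the build of the peak and methylation data were not at hand. The planned counts of marked genes and the planned comparison of osdrm2 tags by CHG methylation of gene bodies were not run, and window classes replaced gene classes for methylation. Sequences outside the 12 chromosomes were left out of all comparisons, as were blank tag values (535 for WT-2 and 530 for osdrm2).

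The steps were tested on simulated data with known changes. With the read depths of chromosome 12, the bin test recovered 99.0% of 200 bins changed by 60 points among 48042 CG bins, 46.5% of 200 bins changed by 30 points among 58476 CHG bins, and 79.0% of 200 bins changed by 15 points among 87971 CHH bins, with 1, 1 and 0 false calls. With the reads of both libraries doubled, the CHG share was 81.0%. The tag ratios recovered 100.0% of 200 genes changed 4-fold among 48510 genes, with 1 false call. The simulated reads and tags held counting error alone, with no further spread between libraries. The false calls therefore do not estimate those between real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and R 4.3.3 were used, with seed 20.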

Results

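H3K27me3, SDG711 binding and DNA methylation were measured in rice leaves of DongJin background collected 12 days after germination. The 7 libraries form 7 groups with 1 library each. H3K27me3 ChIP-seq of culture-regenerated wild type (crWT) held 20802056 tags and that of plants overexpressing SDG711 (SDG711OX) held 9438420 tags. ChIP-seq with an antibody against SDG711, an E(z)-type H3K27 methyltransferase, held 20533075 tags. BS-seq of crWT listed 77.9 M cytosines on the 12 chromosomes at a mean of 11.9 reads, and BS-seq of SDG711OX listed 64.4 M at 8.50 reads. H3K27me3 tags over genes came to 15268455 for osdrm2 and 16477904 for the wild type named WT-2. With 1 library per group there was no replicate error. All intervals below are 95% intervals that cover counting error only, and no p-value between conditions was computed.

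H3K27me3 peaks were more numerous and narrower in SDG711OX than in crWT. The SDG711OX library had 11627 peaks with a median width of 1444 bp and a median enrichment of 4.17-fold, and crWT had 7759 peaks with 2321 bp and 2.89-fold. With a score of at least 100, 5499 SDG711OX and 4873 crWT peaks were left, and with an enrichment of at least 5, 2780 and 139. The peaks covered 19.9 Mb in SDG711OX and 21.9 Mb in crWT. Of the crWT peaks, 5334 (68.7%, Wilson interval 67.7 to 69.8) overlapped a peak of SDG711OX, and 2425 did not. Of the SDG711OX peaks, 5633 (48.4%, 47.5 to 49.4) overlapped a crWT peak and 5994 did not.

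Random placement of the peaks within chromosomes gave an overlap of 13.5% for crWT peaks and 9.32% for SDG711OX peaks. The share of crWT peaks overlapped by SDG711OX peaks ranged from 61.3% to 72.5% between chromosomes. With a fold enrichment of at least 5, the share of SDG711OX peaks overlapped by crWT fell to 3.60%, since 139 crWT peaks passed that limit. The random overlap was computed for the full lists only, so 3.60% cannot be set against 9.32%. The crWT library held 20802056 tags and the SDG711OX library 9438420, and the peak calls had no control library. Peak numbers, widths and enrichments were thus not compared at equal depth. The lowest listed enrichment was 2.08-fold in SDG711OX and 1.73-fold in crWT. Peaks held 16.6% of the tags in SDG711OX and 14.7% in crWT.

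Single regions with H3K27me3 peaks in 1 of the 2 libraries were found on several chromosomes. Away from chromosome starts, the SDG711OX peaks of highest enrichment without a crWT peak lay on chromosome 2 from 18835726 to 18836817 (8.93-fold, 96 tags) and on chromosome 7 from 18393624 to 18394636 (8.82-fold, 79 tags). The chromosome 7 peak held no listed BS-seq cytosine in either library, so read depth there could not be checked. The crWT peaks of highest enrichment without an SDG711OX peak lay on chromosome 11 from 18203145 to 18204322 (7.81-fold, 179 tags) and on chromosome 4 from 17928941 to 17930987 (6.87-fold, 357 tags). The 5 crWT peaks of highest enrichment (10.4-fold to 14.2-fold) all started in the first 2500 bp of chromosomes 2, 4, 5, 8 and 10. In crWT, CHH methylation in these peaks was 48.6% to 86.6%, against 6.04% over all shared cytosines. BS-seq depth there was 0.899 to 2.77 times the chromosome median in crWT. Without a control library, a high read depth cannot be told from enrichment at these sites. Chromosome starts also held the highest peak of SDG711OX (30.8-fold, chromosome 2) and of the SDG711 library (20-fold, chromosome 2).

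SDG711 peaks lay on H3K27me3 regions more often than random placement gave. Of 11214 SDG711 peaks, 2335 (20.8%, interval 20.1 to 21.6) overlapped a crWT H3K27me3 peak and 4235 (37.8%, 36.9 to 38.7) overlapped an SDG711OX peak. Among H3K27me3 peaks of SDG711OX without a crWT peak, 2273 of 5994 (37.9%, 36.7 to 39.2) carried an SDG711 peak. Among crWT peaks also found in SDG711OX, 2039 of 5334 did (38.2%, 36.9 to 39.5), and among crWT peaks without an SDG711OX peak 243 of 2425 did (10.02%, 8.89 to 11.3). Of the 16.9 Mb under SDG711 peaks, 11.2 Mb lay under neither H3K27me3 list.

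In 1000 random placements, SDG711 peaks overlapped crWT peaks at 8.92% and SDG711OX peaks at 9.85%. The random means were 9.34% for the SDG711OX peaks without a crWT peak, 13.1% for the shared crWT peaks and 11.4% for the crWT peaks without an SDG711OX peak. With a fold enrichment of at least 5, an added alternative that 283 SDG711 peaks and 139 crWT peaks passed, the SDG711 overlaps were 6.01% with crWT and 26.5% with SDG711OX. No random placement was run at that limit, so these shares cannot be set against the random means of the full lists. The 2 H3K27me3 lists were called at a p cutoff of 1e-05 and the SDG711 list at 1e-09. The label of the SDG711 library gives no SDG711OX genotype, so binding in the overexpressing plants was not measured.

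**Figure D1:**
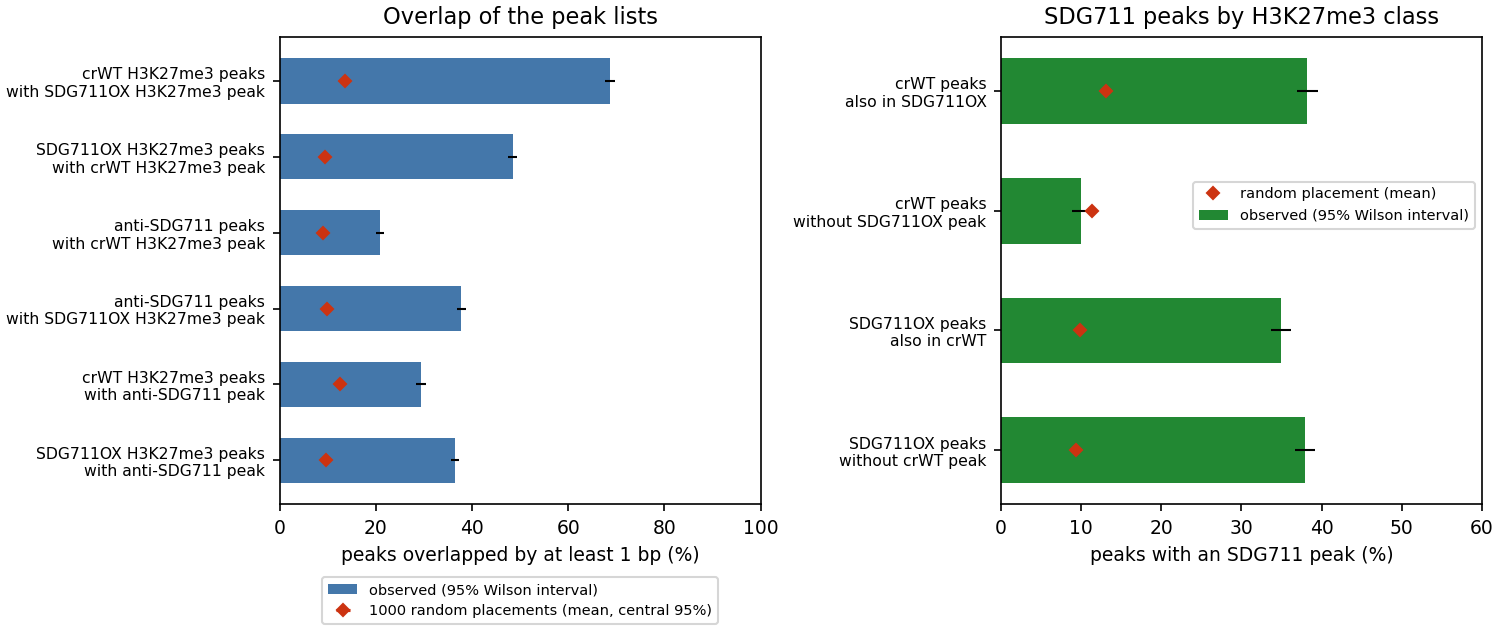
Left, percent of the peaks of each list overlapped by at least 1 bp by a peak of another list (bars with 95% Wilson intervals) and the mean and central 95% of 1000 random placements (diamonds). Right, percent of H3K27me3 peaks with an SDG711 peak by class, with the random mean: crWT peaks without an SDG711OX peak stood at 10.02%, and SDG711OX peaks without a crWT peak at 37.9%.

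DNA methylation was lower in SDG711OX than in crWT in all 3 sequence contexts. Over 53.7 M cytosines with at least 4 reads in both libraries, CG methylation was 67.2% in crWT (interval 67.17 to 67.19) and 61.7% in SDG711OX (61.67 to 61.69). CHG methylation was 31.1% (31.12 to 31.14) and 25.9% (25.94 to 25.96), and CHH methylation was 6.04% (6.041 to 6.045) and 5.37% (5.363 to 5.368). The level was lower in SDG711OX on 12 of 12 chromosomes in each context. By chromosome, the difference ran from -5.16 to -6.19 points in CG, from -4.61 to -5.98 points in CHG and from -0.441 to -0.868 points in CHH. Averaged per cytosine rather than per read, the differences were -3.29, -3.06 and -0.380 points. These are values of 1 library each, and cytosines do not stand in for replicate plants. The methylation intervals and the bin tests count a read anew at each cytosine it covers, as if independent. They are therefore too narrow even for counting error.

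Bins of 200 bp with lower methylation in SDG711OX outnumbered bins with higher methylation in each context. In CHG, 39723 of 922520 bins were lower and 3015 higher, in CG 8453 of 770877 were lower and 2361 higher, and in CHH 14954 of 1335491 were lower and 8486 higher. Lower CHG bins made up 7.15% (interval 6.78 to 7.55) of the bins in SDG711-bound windows without H3K27me3. They made up 4.29% (4.24 to 4.33) in windows without any peak, 5.42% (5.08 to 5.78) in windows with H3K27me3 in SDG711OX alone, 3.36% (3.16 to 3.58) in windows with H3K27me3 in crWT alone, 7.71% (6.76 to 8.77) in SDG711-bound windows with H3K27me3 in SDG711OX alone and 2.71% (2.46 to 2.99) in windows with H3K27me3 in both. SDG711-bound windows with H3K27me3 in both had 3.29% (2.60 to 4.17) lower CHG bins. In the SDG711-bound windows without H3K27me3, higher CHG bins were 0.618% (0.511 to 0.747), against 0.313% without any peak. In the same windows, lower bins were 0.622% (0.521 to 0.742) of the CG bins, against 1.09% without any peak, and 0.732% (0.637 to 0.841) of the CHH bins, against 1.04%, with 210 CHH bins higher and 196 lower. CHG methylation in crWT was 65.3% in these windows and 30.3% without any peak, and the bin shares were not matched on level. Each bin passed Fisher's exact test at an adjusted p of 0.05 (Benjamini-Hochberg) with a difference of at least 40 points in CG, 20 in CHG or 10 in CHH. The test compares these libraries, not the conditions. The counts moved by over 1.5 times with bin width, read minimum or minimum difference for most contexts, with more lower than higher bins in every setting run.

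Windows of 1 kb bound by SDG711 without H3K27me3 had the highest CG and CHG levels of the peak classes. In these 10544 windows CG was 85.5% in crWT (interval 85.46 to 85.55) and 82.2% in SDG711OX (82.18 to 82.30), CHG 65.3% (65.2 to 65.4) and 59.2% (59.1 to 59.3), and CHH 4.49% (4.47 to 4.50) and 4.199% (4.18 to 4.22). In the 9216 windows with H3K27me3 in both libraries, CHG was 28.1% (28.0 to 28.1) and 24.4% (24.4 to 24.5) and CHH 9.07% (9.05 to 9.08) and 8.01% (7.99 to 8.03). In the 10088 windows with H3K27me3 in SDG711OX alone, CHG was 33.1% (33.1 to 33.2) and 27.5% (27.4 to 27.6) and CHH 8.36% (8.34 to 8.37) and 7.37% (7.35 to 7.39). In the 9878 windows with H3K27me3 in crWT alone, CHG was 25.5% (25.4 to 25.5) and 20.7% (20.7 to 20.8) and CHH 6.65% (6.64 to 6.66) and 5.74% (5.72 to 5.75).

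The change from crWT to SDG711OX was set beside peak-free windows of the same crWT level and similar reads. SDG711-bound windows had a median CHG change of -1.997 points, above all 10000 matched sets (mean of their medians -3.27), and a median CG change of -1.57 points, also above all of them (-3.27). Windows with H3K27me3 in crWT alone had a median CHG change of -1.59 points, below all 10000 matched sets (-0.828), and a median CG change of -3.33 points (-2.49). Windows with H3K27me3 in SDG711OX alone had a median CHG change of -0.885 points, at percentile 0.68 of the matched sets (-0.718). Their mean change, an added statistic, was -4.06 points, below all matched means (-3.58). At a minimum of 10 reads the median stood at percentile 22.8 and the mean at 60.2. With added matching on listed cytosines both lay below all 1000 matched sets. With the added any-overlap class the median lay below all of them and the mean at percentile 1.3. These windows had a median CHH change of 0.00 points (matched -0.0588). Windows with H3K27me3 in both had a median CHG change of -0.422 points, at percentile 3.27 (matched -0.313), and at a minimum of 10 reads the side turned, with a median 0.401 points above matched windows at percentile 99.1. Their mean CHG change, an added statistic, was -2.54 points and above all matched means (-2.96), so that median and mean stood on opposite sides. In CHH the same held for SDG711-bound windows, with a median of -0.0814 points below all matched sets and a mean of -0.299 points above all matched means (-0.456). Windows are neighbours on chromosomes, so the percentiles describe these libraries and are no test of the overexpression.

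**Figure D2:**
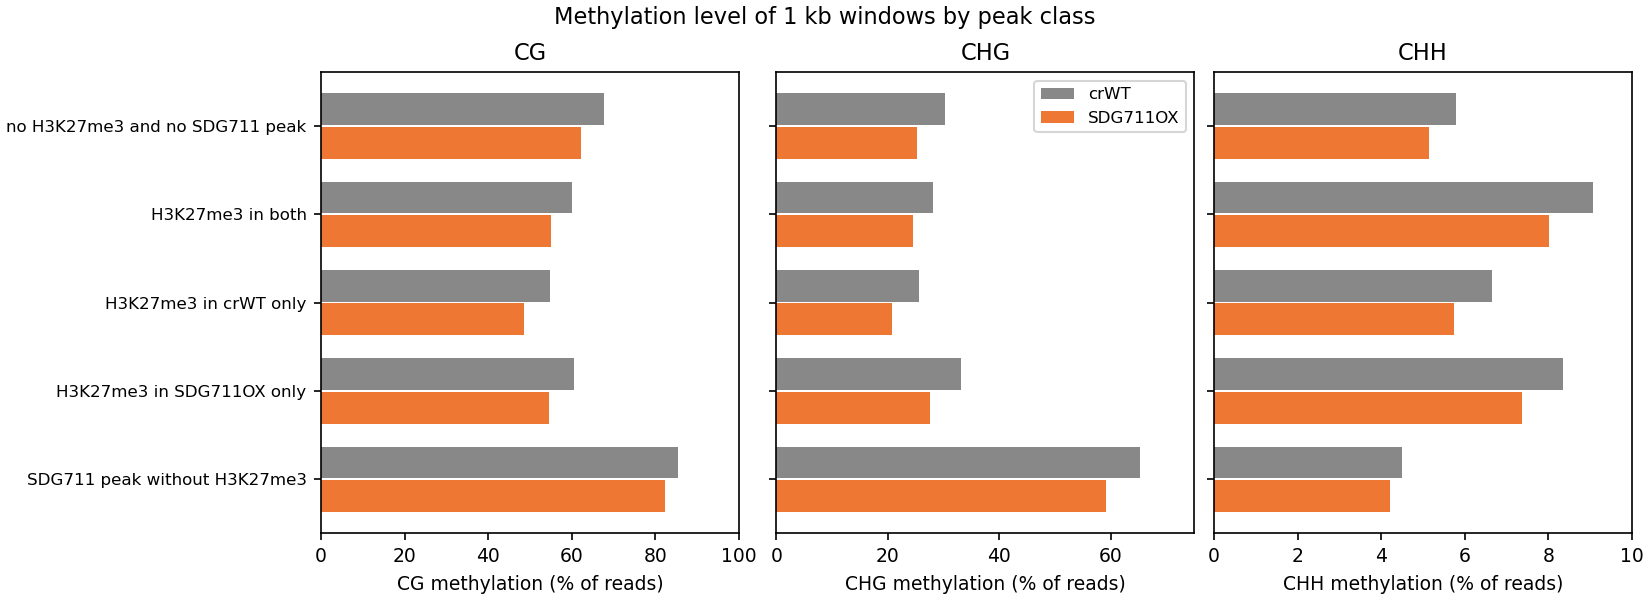
Read-weighted methylation in percent of reads (horizontal axes) of 1 kb windows by peak class, for crWT (grey) and SDG711OX (orange), in CG, CHG and CHH. The SDG711OX bar is the shorter one in each class and context, as in SDG711-bound windows without H3K27me3 (CHG 65.3% and 59.2%), and the horizontal scale differs between contexts.

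H3K27me3 tags per gene in osdrm2 stood within 2-fold of WT-2 for most genes. Of 48510 genes, 382 were at least 2-fold higher in osdrm2 and 518 at least 2-fold lower, so that 42.4% of these genes were higher. With scaling by the trimmed mean of M values (TMM), 264 of 48487 genes were higher and 777 lower, so that 25.4% were higher. The median log2 ratio of all genes was 0.09, and 0.01 with TMM. The 25% of genes with the highest tag density had a median log2 ratio of -0.23 (268.6 tags per kb in osdrm2, 312 in WT-2), and -0.32 with TMM. The 25% with the lowest had 0.19 (48.1 and 42.2 tags per kb), and 0.11 with TMM. Within the 10% of highest density, genes under 1000 bp had a median of -0.31 (n = 2094), genes of 1000 to 2000 bp -0.36 (n = 1577), genes of 2000 to 4000 bp -0.21 (n = 808) and genes of 4000 to 8000 bp -0.05 (n = 329). The split by density used the mean of both libraries, and a split by WT-2 density gave -0.28 for the 25% of highest density. A difference in ChIP enrichment between the osdrm2 and WT-2 libraries was not tested, since no control library was at hand. The genotype label of the osdrm2 library reads DongJin, as for WT-2, the title alone names osdrm2, and the labels do not say whether the WT-2 plants were culture-regenerated, although the name of the deposited WT-2 values shares an abbreviation with that of crWT.

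Most genes of the meristem, floral and shoot lists were among the 10% of genes with the highest H3K27me3 tag density: 8 of 8 KNOX and WOX homeobox genes, 15 of 17 MADS-box and floral genes and 11 of 12 shoot architecture genes. MADS2 (64.1 tags per kb in osdrm2 and 59.1 in WT-2), MADS4 (57.3 and 72.5) and SPL14 (107.4 and 167.8) were not. The KNOX and WOX genes had ratios below 0 under both scalings, with a median log2 ratio of -0.18. This stood at percentile 81.3 among 10000 random lists matched on density (random median -0.28). Among lists matched also on gene length, an added alternative, it stood at 45.7 (random median -0.17). Examples were WUS (-0.41, exact interval -0.55 to -0.26), QHB (-0.29, -0.43 to -0.16), OSH6 (-0.29, -0.35 to -0.23) and OSH71 (-0.18, -0.25 to -0.12). The 17 MADS-box and floral genes had a median of -0.01 at percentile 98.8 (97.2 with length), against random medians of -0.18 and -0.11. Of these genes, 7 were above 0 and 10 below, and with TMM 1 above and 16 below. Among them MADS4, a floral organ gene, had -0.34 (-0.63 to -0.05), MADS58 -0.20 (-0.25 to -0.16), MADS2 0.12 (-0.17 to 0.41) and MADS5 -0.08 (-0.14 to -0.02). Of the 12 shoot architecture genes, 11 were below 0 under both scalings, with a median of -0.38 at percentile 8.94 (1.44 with length). The random medians were -0.24 and, with length, -0.19. The 8 members checked against the gene table, which leave out TAW1 and APO1, had a median of -0.34 at percentile 21.7. SPL14, a regulator of tillering, had -0.64 (-0.82 to -0.47), TAW1 -0.64 (-0.77 to -0.51), APO1 -0.51 (-0.63 to -0.39) and FZP -0.46 (-0.58 to -0.33).

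Flowering time genes were spread on both sides of 0. Of 10 members, 5 were above 0 and 5 below (with TMM 4 and 6), with a median of -0.03 at percentile 76.8 (64.3 with length). Hd1, a photoperiod regulator, had -0.46 (-0.75 to -0.18), GI 0.25 (0.08 to 0.43) and Ehd1 0.25 (0.09 to 0.40). The 3 members kept from the diterpenoid clusters were above 0 under both scalings, with a median of 0.17 at percentile 89.8 (82.8 with length): KSL4 0.57 (0.47 to 0.68), CPS2 0.17 (0.10 to 0.24) and CPS4 0.14 (0.00 to 0.27).

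The loci listed for Polycomb repressive complex 2, which deposits H3K27me3, were at low tag density in both libraries. Symbols were paired with locus numbers from memory, and for 5 of the 6 members, SDG711 included, the pair is unchecked because the gene table held no such symbol. The 6 members had a median of 53.0 tags per kb in osdrm2 and 42.4 in WT-2, and 6 of 6 were above 0 under both scalings, with a median log2 ratio of 0.34 at percentile 90.5 (89.98 with length). Random lists were also above 0, with a median of 0.19, and 0.23 with length. SDG711 had 0.21 (0.01 to 0.42), with 52.2 and 45.01 tags per kb. EMF2b had 0.44 (0.27 to 0.61), FIE1 0.42 (0.16 to 0.68) and FIE2 0.35 (0.13 to 0.57). Of the DNA methylation list, ROS1a, a DNA glycosylase gene, was the member kept and had 0.40 (0.22 to 0.57). It lay among the 25% of genes with the lowest density, whose median was 0.19. DRM2 was not analysed here because the locus number paired with it was not among the listed loci.

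Lists of leaf, seed and root genes had medians within the central 95% of random lists under both matchings. The 10 leaf and housekeeping genes had a median of 0.01 (-0.08 with TMM) at percentile 38.3 (48.5 with length), among them EF1A 0.71 (0.30 to 1.14), CAB1R -0.48 (-0.71 to -0.26), RBCS4 0.48 (0.27 to 0.68) and PSBO -0.33 (-0.61 to -0.07). The 6 seed genes had 0.06 (-0.03 with TMM) at percentile 56.5 (21.7 with length), among them RISBZ1 -0.47 (-0.71 to -0.24) and WAXY 0.23 (0.12 to 0.35). The 6 root genes had -0.20 at percentile 49.0 (17.4 with length), with 2 above 0 and 4 below under both scalings, among them NAS1 -0.47 (-0.64 to -0.30) and LSI2 -0.35 (-0.45 to -0.25). No member kept in the lists was at least 2-fold higher or lower. The percentiles describe these 2 libraries and are no test of the genotype.

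**Figure D3:**
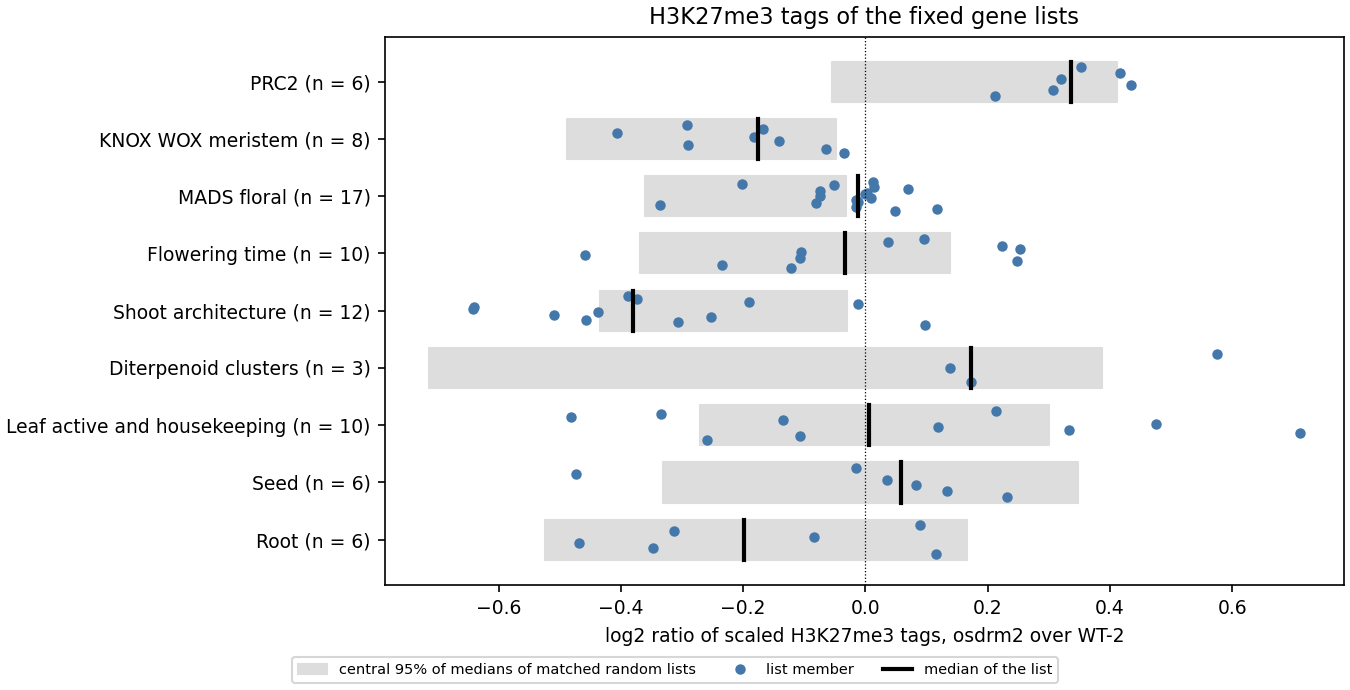
Log2 ratio of scaled H3K27me3 tags, osdrm2 over WT-2 (horizontal axis), for each list member (points) with the list median (black line) and the central 95% of medians of matched random lists (grey). The shoot architecture list had a median of -0.38, and the MADS and floral list had -0.01 with 7 members above 0 and with TMM 1.

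Neighbouring genes on chromosomes 8, 10 and 11 had several times more tags in osdrm2 than in WT-2. The 2 genes with the highest ratios, LOC_Os08g15710 (1065 and 2 tags, log2 ratio 8.56, exact interval 7.31 to 12.21; 6.55 with a pseudocount of 10) and LOC_Os08g15770 (749 and 2 tags, 8.06, 6.80 to 11.71; 6.05), lie close together. The 2 lowest were LOC_Os07g16990 (65 and 1504 tags, -4.40, -4.80 to -4.06) and LOC_Os08g15430 (24 and 431 tags, -4.003, -4.71 to -3.46). Of the 382 genes at least 2-fold higher, 21.2% adjoined another such gene, against a mean of 1.54% and a highest value of 4.71% in random orders. Of the 518 lower genes, 6.56% did (random mean 2.07%, highest 5.21%). The longest run held 12 genes on chromosome 10, from LOC_Os10g05290 to LOC_Os10g05430, with a median of 105.7 tags per kb in osdrm2 and 25.6 in WT-2.

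**Figure D4:**
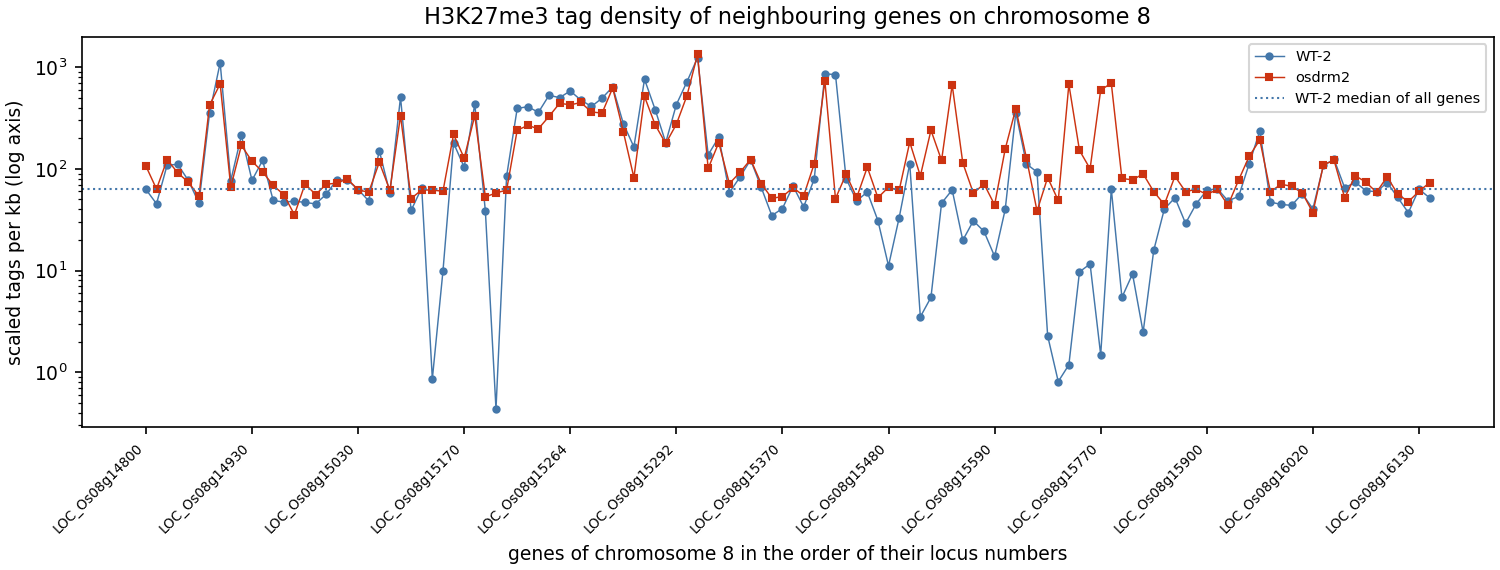
Scaled H3K27me3 tags per kb (log axis) of genes on chromosome 8 in the order of their locus numbers, for WT-2 (blue) and osdrm2 (red), with the WT-2 median of all genes, 63.2 tags per kb, as a dotted line. In the run of 11 genes from LOC_Os08g15660 to LOC_Os08g15830 the median density was 89.3 in osdrm2 and 5.44 in WT-2.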

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

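Of the 7 tests below, 6 were chosen after the result they weigh was seen, and 1, the caller score of SDG711OX peaks, was written before its value was computed.

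BS-seq reads on sequences outside the 12 chromosomes, which no comparison used, held methylation above the limit of a count of 0. In crWT the levels were CG 78.4%, CHG 45.3% and CHH 5.15%, and in SDG711OX CG 74.7%, CHG 39.2% and CHH 4.80%. No explanation of these values was tested.

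SDG711 peaks lay on H3K27me3 peaks found in SDG711OX alone and much less on those found in crWT alone. Cytosine composition and read coverage were weighed by matching windows with H3K27me3 in SDG711OX alone to unmarked windows. The coverage matched was that of crWT BS-seq, not of the ChIP libraries. The bound share was 4.94 times that of the matched windows (1.23 times for windows with H3K27me3 in crWT alone). Against all unmarked windows these ratios were 8.09 and 0.918. The matched measures may thus account for part of the pattern but do not account for the whole of it. Weak peaks that the caller missed in crWT may account for part of it, since of the 2907 SDG711OX peaks with the highest scores 22.5% lacked a crWT peak, a share between the limits of 10% and 25% set in the prediction. Peaks missed in SDG711OX, which held 9438420 tags against 20802056 in crWT, were not tested as a source of the peaks found in crWT alone. Those had a median enrichment of 2.80-fold, against 2.93-fold for the shared crWT peaks. A technical trait shared by the SDG711OX and SDG711 libraries, such as open chromatin in ChIP without a control library, remains open. A gain of H3K27me3 at SDG711 sites in the overexpressing plants is a candidate explanation that 1 library per group cannot separate from these.

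Methylation was lower in SDG711OX in each context. Less complete bisulfite conversion in crWT would raise CHH by at least as many points as CHG, but over all shared cytosines CHH differed by -0.677 points, too little to account for the falls in CG and CHG. In windows with CG methylation under 1% in SDG711OX, whatever their crWT level, CHH differed by -0.141 points, so conversion does not account for the whole CHH fall and could account for a part. The weight of cytosines with many reads does not account for the direction, since the mean per-cytosine CG difference was -3.29 points, although it is smaller than the read-weighted one. Mapping differences and the regeneration history of the plants could contribute and were not tested, and an effect of SDG711 overexpression cannot be told from a difference between 2 libraries.

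Runs of neighbouring genes had many more tags in osdrm2 than in WT-2. H3K27me3 gained in osdrm2 or lost in WT-2, on DNA present in both, would leave WT-2 at the density of unmarked genes. The 33 genes in the 4 runs of at least 5 genes had a WT-2 median of 11.6 tags per kb (interval over resampled runs 5.44 to 21.05). This lay below percentile 5 of all genes (35.5) and the median of 44.7 (40.5 to 52.2) in the 349 other genes at least 2-fold higher. The 349 were not alike in ratio, with 329 in the lowest class of log2 ratios against 6 of the 33 run genes. A high ratio itself selects genes low in WT-2. The low median argues against gain or loss for the runs as a whole but does not exclude them. A later description took other stretches of as many neighbouring loci as each run. Those with a WT-2 median as low as the run made up 0.029% to 0.73% of stretches. Of these, 396 of 400, 16 of 16, 248 of 249 and 144 of 153 were under 2 times that median in osdrm2. Elsewhere, stretches this low in WT-2 were thus nearly always low in both libraries. The low median does not speak to the 8 genes at or above percentile 5, such as LOC_Os11g10820 with 114.5 tags per kb in WT-2, for which both stay open. DNA that is absent from the WT-2 plants, or did not map there, may account for the others, but its test did not decide: the share under percentile 5 was 75.8%, against 50.7% in other genes weighted to the same log2 ratios, a difference of 25.1 points (-0.544 to 55.4), and 3 other genes reached the highest class of ratios. Among these 3 were LOC_Os08g15120 and LOC_Os08g15220, with 0.858 and 0.433 tags per kb in WT-2, which lie near the runs on chromosome 8. The comparison genes may thus share the cause of the runs, so this difference cannot decide. Genome sequence of the plants was not at hand, and the labels do not give the plant history of WT-2, although the name of its deposited values shares an abbreviation with that of crWT, the culture-regenerated wild type.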

How the results depend on the processing

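Settings called added below, the density classes and the list checks were chosen after seeing the data. No paired analysis was possible because each group holds 1 library. Among alternative values for the comparisons, 97 stayed within their limits and 45 moved. For named genes and for windows in CG and CHH, 172 stayed, 47 moved and 3 reversed; of the named genes, 30 moved with TMM and 8 with a pseudocount of 10. The cause was not tested unless named.

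Peak overlaps exceeded random placement in the main setting, and no random placement was run for the other settings. With a score of at least 100, crWT peaks overlapped by SDG711OX were 55.9%, SDG711OX by crWT 50.2%, SDG711 by crWT 14.3% and SDG711 by SDG711OX 25.02%. With at least 50% of the peak overlapped, these were 47.4%, 46.6%, 17.4% and 36.01%. With an enrichment of at least 5, crWT by SDG711OX was 71.9% and SDG711OX by crWT 3.60%, since few crWT peaks passed. The same limit, added for SDG711, gave 6.01% by crWT and 26.5% by SDG711OX.

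The methylation differences stayed below 0 in CG, CHG and CHH: -6.19, -6.31 and -0.510 points with the deposited minimum, -4.99, -4.55 and -0.667 at 10 reads, and -3.29, -3.06 and -0.380 per cytosine. Lower bins outnumbered higher bins in each setting. At 10 reads, where fewer bins were tested, CG had 626 higher and 1370 lower, and CHG 970 and 9589. In 500 bp bins, CG had 731 higher and 4079 lower, CHG 1597 higher, and CHH 2847 higher and 5888 lower. Halved differences, which admit more bins by construction, gave 10160 and 37762 in CG and 20229 and 33324 in CHH. In simulation, 46.5% of 30-point CHG changes were recovered, and 81.0% with reads doubled.

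For windows, the median change minus matched windows kept its sign in CHG for 3 of 4 classes. For H3K27me3 in both it was 0.401 points at 10 reads (main -0.108) and -0.236 with added matching on listed cytosines. With the added any-overlap class it was -0.621 for H3K27me3 in crWT alone and 0.814 for SDG711. At 10 reads, CG for H3K27me3 in both reversed to 0.199 and CHH for SDG711OX alone to -0.00743.

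Genes at least 2-fold higher and lower were 695 and 882 with no filter, which adds genes with few tags. The 25% of genes with the highest density had -0.28 by WT-2 density, -0.32 with TMM and -0.21 with no filter. TMM moved the median of the MADS and floral list to -0.10 and of the diterpenoid list to 0.085, and reversed MADS17 from 0.07 to -0.017, since it lowered the median of all genes by 0.09. The other list medians stayed within their limits, and those of leaf and seed genes changed sign with TMM. The leaf list was also below 0 without the list check (-0.06) and with checked members alone (-0.13). With random lists matched also on length (added), the median minus random lists changed sides for KNOX and WOX (0.11 to -0.0085) and for seed genes (0.0285 to -0.101). The shoot list left their central 95% (percentile 1.44) and the MADS list entered it (97.2).

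Not run were the planned settings for marked genes (score of at least 100, 25% of the gene body), for gene bodies and 1 kb upstream, and for CHG methylation of at least 10% or 30% in gene bodies, since gene coordinates were not at hand.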

Other observations

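The DNA methylation list without the check of its members, an alternative chosen after the data were seen, had 4 measured members above 0 with a median log2 ratio of 0.46 at percentile 97.6 of random lists matched on density. Among its members left out of the main lists, MET1a had 0.52 (exact interval 0.07 to 0.99), MET1b 0.73 (0.34 to 1.14) and CMT3a 0.07 (-0.19 to 0.33), or -0.02 with TMM. The diterpenoid list without the check had 4 members above 0 and 2 below, with a median of 0.16 at percentile 98.6. CYP76M7 had -0.58 (-0.72 to -0.44) there. The pairing of these symbols with their locus numbers is uncertain.

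By chromosome, genes at least 2-fold higher in osdrm2 outnumbered lower ones on chromosomes 8 (47 and 33), 11 (49 and 26) and 12 (32 and 24). On chromosome 8, 19 of the 47 higher genes lay in runs of at least 3 neighbours between LOC_Os08g15510 and LOC_Os08g15830, and outside these runs 28 were higher and 33 lower. On chromosome 11, 38 higher genes lay outside such runs. Chromosome 1 had 36 higher and 70 lower genes, and chromosome 6 had 26 and 57.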
